A study of Drosophila melanogaster with 12 samples.

How the data were processed

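Gene expression was measured in heads of y w Drosophila melanogaster at 6 hours of a light/dark day (LD) and at the same 6 hours of the following day in constant darkness (DD), 4 h apart, with 1 Affymetrix array per time point. Per the labels, heads were separated from frozen flies by sieving, RNA was extracted with Rnazol or Trizol and purified on columns, and labelled cRNA was made from 25 µg of RNA. The log2 values were made by the authors with RMA (background correction, quantile normalization and summary per probe set) and were used as deposited. The version of RMA, and whether these 12 arrays were normalized together with others, is not given in the sources used here. The values lay between 1.96 and 13.9, and the quartiles of the arrays nearly coincided. No filter was applied. Of 14010 probe sets, the 44 control probe sets were set aside and 13966 were tested. Among these, 12443 carried 1 gene symbol, 327 several and 1196 none, and 10844 genes were named. Probe sets were linked to current symbols through a table of gene names and synonyms, and no genome positions were used. No raw probe intensities were analysed here.

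All fits were made with limma 3.58.1 in R 4.3.3, with moderated statistics, on the 12 arrays, and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. The daily rhythm was an F-test of a cosine and a sine of 24 h with a term for the regime (8 residual degrees of freedom). Rhythms in LD and in DD, and their difference, came from a fit with a separate curve for each regime (6 residual degrees of freedom). The mean level in DD minus that in LD was tested beside the cosine and sine. The light-dependent difference was tested in a fit with 4 groups of 3 arrays, by regime and by hours 2, 6 and 10 against hours 14, 18 and 22. Amplitudes are from the mean to the peak of the fitted curve, in log2 units, and errors of fitted values are standard errors. The number of arrays, 6 in each regime, limits the precision.

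In all, 20 gene lists were compared with the other genes by limma's camera in 4 contrasts, with a preset correlation of 0.01 and with an estimated one, each gene standing by its brightest probe set. They covered the core clock, genes known as rhythmic in fly heads, phototransduction, chaperones, antimicrobial and immune genes, detoxification, fat body and lipids, carbohydrates and feeding, neurons and synapses, glia, female and male markers, ovary, testis and accessory gland, flight muscle, midgut, cuticle and pigment, cytosolic ribosomal proteins, the proteasome and oxidative phosphorylation. Adjustment was over the 80 tests. Members were also counted past the threshold over all probe sets and when adjusted over the list alone. The mean levels of 10 lists of cell types and sexes were compared between regimes by two-sided exact permutation tests. The aim was to see whether carry-over of body parts or the mix of sexes moved with the regime.

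The groups, comparisons, tests, gene lists and the rule for naming genes were chosen before the data were examined. The rule named every measured core clock gene. For the daily rhythm it named up to 12 genes with the largest amplitude among those called, for each of the daytime and night hours. For the other comparisons it named up to 10 genes with the largest effect per direction, or the 5 with the smallest p-values where none was called. For each list it named up to 4 members with the smallest p for rhythm and 2 for mean level. A gene was named by its brightest probe set. The genes Prosbeta6, elav, Syn, Rdl, retinin, inaD, Cyp6a23, Tep4, Rel, Pepck2 and ND-51, and the dimmer probe sets of Tsp, Vajk2 and Fs(2)Ket, fell outside it, and each was chosen after its values were seen.

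The signal of the 5′ probe sets of the actin, GAPDH and eIF-4a control transcripts minus that of their 3′ probe sets was averaged per array. Its use as a covariate, and the omission of the 4 arrays in which it was lowest, were chosen after the data were seen. The alternatives tried were the brighter part of the probe sets, quantile normalization again, centring on array medians, an intensity trend with a robust prior, leaving out each array, a linear trend or no term for regime, hour as a factor with 5 degrees of freedom, 1 probe set per gene, each day alone, hour of day as a block, no cosine and sine, the mid-day axis in place of the step between daytime and night hours, and the mean of a gene's probe sets. Counts of calls were also compared with those of 100 orders or splits of the arrays, the observed one included, or of the 32 exchanges of LD and DD within hours. The fits were tested on simulated data of 13966 probe sets, 200 of them changed, with noise drawn independently for each probe set and array. Structure shared between probe sets or arrays was not simulated, so the false calls given here may not carry over to the real arrays. A rhythm of amplitude 0.5 log2 was called in 83% of changed probe sets over both days and in 60.5% in LD, a difference of rhythm of that size in 19.5%, a mean difference of 1 log2 in 94.5% and a light-dependent difference of 1 log2 in 75%, with between 3 and 15 false calls.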

Results

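Gene expression was measured in heads of adult y w Drosophila melanogaster, a laboratory strain that carries mutations in the body colour gene yellow and the eye colour gene white. The flies had spent 3 days in cycles of 12 h light and 12 h darkness before sampling began. Heads were then collected every 4 h over a further light/dark day (LD) and over the following day in constant darkness (DD), at hours 2, 6, 10, 14, 18 and 22 counted from actual or subjective lights-on. Each sample was a pool of roughly 100 to 200 heads hybridised to 1 Affymetrix array, which gave 12 arrays, 6 in LD and 6 in DD. The deposited values were log2 expression levels for 13966 probe sets, besides 44 control probe sets, and the median level per array lay between 5.37 and 5.40. Pairs of arrays correlated across probe sets with r between 0.973 and 0.995, where probe sets are not independent replicates. Each time point was 1 array, so the hours of the second day served as replicates of the first. Nothing in the labels says how far the pools differ in origin, so the p-values measure the spread between these arrays, part of which may be technical, and the number of arrays limits the precision.

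The arrays differed in the signal from the 5′ ends of 3 control transcripts (actin, GAPDH and eIF-4a) relative to their 3′ ends, a measure of how complete the labelled RNA was. The 5′ minus 3′ signal averaged −1.70 ± 0.19 log2 (SD, n = 6) in LD and −1.93 ± 0.45 (SD, n = 6) in DD, a difference within the spread of the arrays (two-sided exact permutation test over 924 splits, p = 0.297). The lowest signals were those of LD hour 2 (−2.02) and of the night arrays of DD, at hour 14 (−1.89), hour 18 (−2.51) and hour 22 (−2.45), whereas the other arrays lay between −1.76 and −1.51. At LD hour 2 and DD hour 14 the low mean came from actin and GAPDH alone. The eIF-4a signals of those arrays (−1.29 and −1.18) were the highest of all, while DD hours 18 and 22 were low in all 3 transcripts. The signal was related to the first principal component of all arrays, which held 29.1% of the variance. Pearson's r was 0.793 (permutation p = 0.00222), Spearman's rho was 0.783 (permutation p = 0.00386), and r was 0.917 without the 2 arrays farthest from the median signal. Correlations of the signal with the mean levels of the 20 gene lists were also computed, were not tested by permutation and are not given, so these p-values are not adjusted for them.

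**Figure D1:**
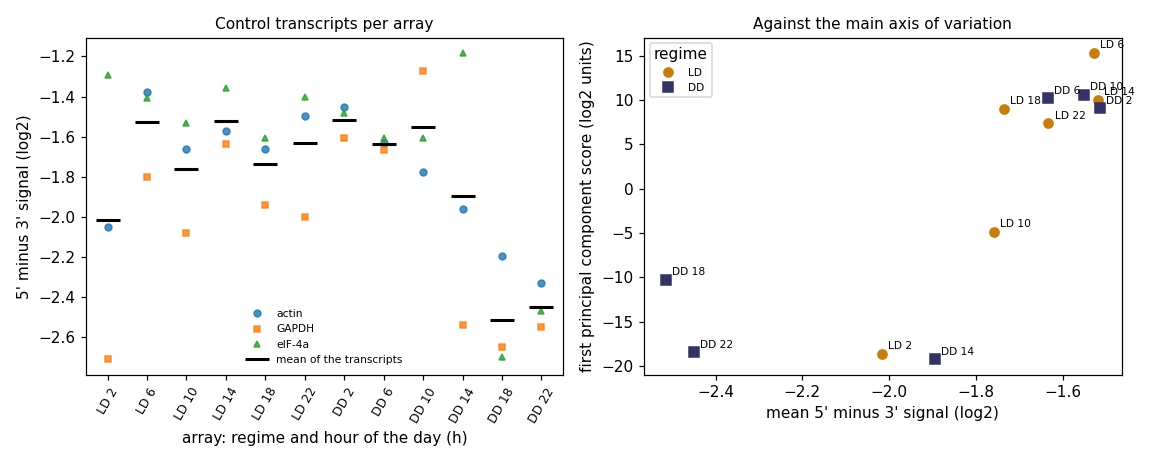
The left panel plots the 5′ minus 3′ signal (log2) of the 3 control transcripts on each array, with a bar at their mean, and the right panel plots that mean against each array's score on the first principal component, with LD arrays as circles and DD arrays as squares. LD hour 2 and the DD arrays of hours 14, 18 and 22 have the lowest mean signals, between −2.51 and −1.89, and scores between −19.3 and −10.3.

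The series was designed to follow daily rhythms of transcripts in the head through a light/dark cycle and into darkness. Transcripts of the clock genes vrille (vri) and timeless (tim) rose and fell with a 24 h period over both days and were highest early in the night. The product of vri represses Clk, and the product of tim acts with that of period (per) in the main feedback loop of the clock. The fitted amplitude of vri (NCBI gene 33759) was 0.86 ± 0.06 log2 (SE, 12 arrays), a peak-to-trough ratio of 3.28, with the peak at hour 13.7 (limma, adjusted p = 6.04e-04). That of tim (NCBI gene 33571) was 1.02 ± 0.09 log2, a ratio of 4.14, with the peak at hour 15.0 (adjusted p = 0.00485). Gclm (NCBI gene 248194), the modifier subunit of the enzyme that starts glutathione synthesis, cycled with an amplitude of 0.38 ± 0.04 log2, a ratio of 1.69, and a peak at hour 11.8 (adjusted p = 0.0497). No other probe set passed Benjamini-Hochberg adjustment over 13966, and 654 had an unadjusted p under 0.05, where uniform p-values would give 698 and permuted hours gave a median of 523, with 36 of 100 orders giving as many as observed. vri and tim stayed past the threshold when any 1 array was left out. The call of Gclm held without LD 2 but was lost without each of the other arrays in turn, with adjusted p from 0.0971 without LD 6 to 0.298 without LD 22. It was also lost with the 5′ minus 3′ signal as a covariate (adjusted p = 0.0625), quantile normalization again (0.104), centred arrays (0.0567), a robust prior (0.133), a linear trend (0.0544) and without the 4 arrays of lowest 5′ signal (0.123), with amplitudes from 0.36 to 0.43 log2. With hour as an unordered factor 0 probe sets passed (limma). Without the 4 arrays of lowest 5′ signal 1 probe set passed, that of vri, while tim had an amplitude of 1.11 log2 (adjusted p = 0.0573) with the 8 arrays left. Without a term for the regime tim had adjusted p = 0.0901.

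Of the 19 core clock genes fixed before the data were examined, 14 were measured. 2 were called over all probe sets, and 6 passed when adjusted over the list alone. Besides vri and tim, these were per, with an amplitude of 0.34 ± 0.07 log2 and a peak at hour 16.3, the transcription factor gene Pdp1 (0.25 ± 0.05, hour 15.7), the blue-light photoreceptor gene cry (0.41 ± 0.08, hour 7.37) and Clk (0.42 ± 0.10, hour 1.62), which encodes the activator of per and tim. The list-alone adjusted p of these 4 lay between 0.00697 and 0.00967. The members cyc, slmb, Pdf, wdb, cwo, dco, jet and tws did not pass and had amplitudes from 0.04 to 0.22. For cwo, a dimmer probe set had an amplitude of 0.31 ± 0.09 where the brightest had 0.05 ± 0.04, and the dimmer probe sets of tim had amplitudes of 0.73 ± 0.16 and 0.08 ± 0.04. Among 100 permutations of hours within each day, the observed one included, only the observed order gave as many members with an unadjusted p under 0.05 (permutation p = 0.01, the smallest they can give, and 0.1 after adjustment over the lists). With the 5′ minus 3′ signal as a covariate, the amplitudes of tim and vri were 1.08 and 0.86 (adjusted p = 3.84e-04 and 9.35e-04).

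**Figure D2:**
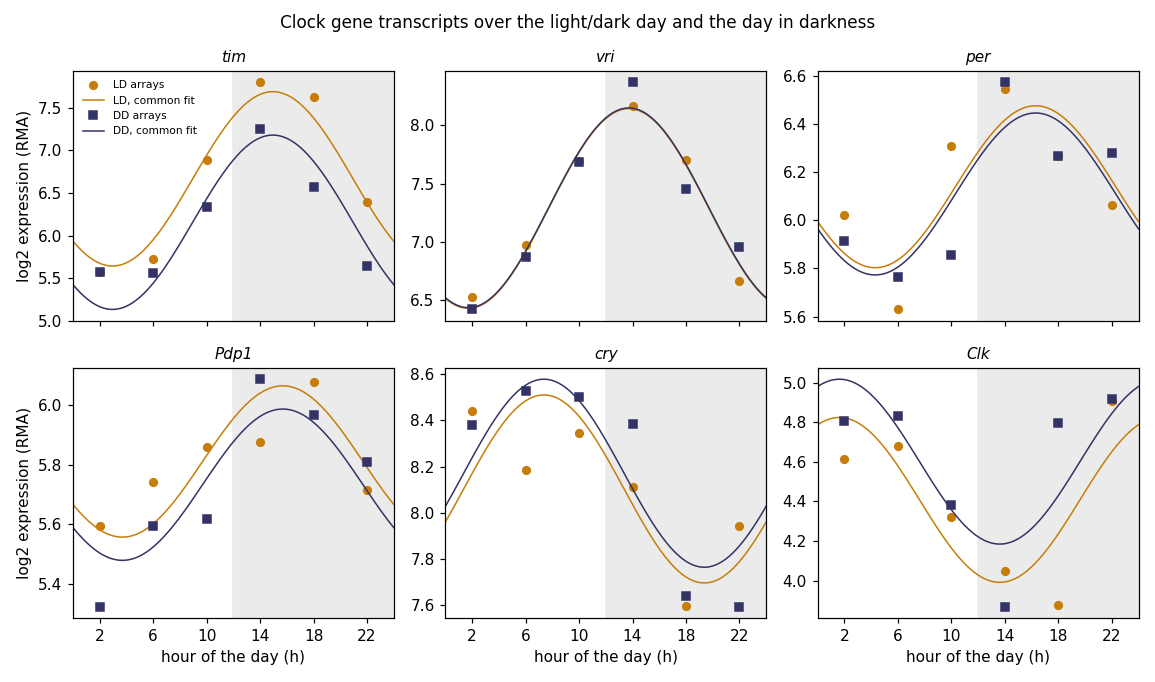
Log2 expression (vertical axis, RMA values) of 6 clock genes against the hour of the day, with LD arrays as circles, DD arrays as squares, and the 24 h curve of the fit over both days drawn at each day's mean; the shaded hours were dark in LD. The curves of tim, vri, per and Pdp1 peak between hours 13.7 and 16.3, and that of Clk at hour 1.62.

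Some genes known from earlier work as rhythmic in fly heads also cycled here. Of 22 measured of the 23 in that list, 1 (Gclm) was called over all probe sets and 14 passed when adjusted over the list alone, though such lists may rest in part on these same libraries and are then not independent evidence. Usp8 had an amplitude of 0.86 ± 0.12 log2 with a peak at hour 13.3, and Slob, which encodes a protein that binds the Slowpoke potassium channel, had 0.49 ± 0.08 at hour 13.9 (list-alone adjusted p = 5.58e-04 and 0.00178). Cuticle protein gene Cpr72Ec (0.80 ± 0.12, hour 3.98) and the glucuronosyltransferase gene Ugt35B1 (0.87 ± 0.15, hour 3.67) peaked in the morning (list-alone adjusted p = 0.00134 and 0.00178). The light-activated channel gene trpl peaked before dusk (0.40 ± 0.09, hour 9.93, list-alone adjusted p = 0.00741). It was also a member of the phototransduction list, and within that list it did not pass. For Slob and Ugt35B1, dimmer probe sets had amplitudes of only 0.04 ± 0.03 and 0.12 ± 0.07. Only the observed order of hours among 100 permutations gave as many members (15) with an unadjusted p under 0.05 (permutation p = 0.01, 0.1 after adjustment).

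Some subunits of the proteasome, the complex that degrades ubiquitin-tagged proteins, peaked late in the day. None of the 40 measured subunits was called over all probe sets, and 6 passed when adjusted over the list alone, namely Rpn12, Prosalpha5, Rpt4, Prosalpha4, Rpn11 and Prosbeta6. Rpn12 had an amplitude of 0.28 ± 0.04 log2 with a peak at hour 9.12 (list-alone adjusted p = 0.00117), and Rpt4 had 0.35 ± 0.07 at hour 9.31 (0.0211). The list was shifted on both axes of the rhythm, with a median of −0.09 log2 for dawn over dusk (camera, adjusted p = 3.64e-06) and of 0.08 for mid-day over mid-night (adjusted p = 1.76e-05). Neither call held with an estimated correlation between genes (adjusted p = 0.216 with an estimated correlation for both), and 10 of the 40 subunits had the opposite sign for dawn over dusk. Of 100 permutations of hours, 3 gave as many members with an unadjusted p under 0.05 as the observed 11 (permutation p = 0.03, 0.2 after adjustment over the lists). With the 5′ minus 3′ signal as a covariate, the dawn over dusk median was −0.09 (adjusted p = 2.06e-05), whereas the mid-day over mid-night median went down to 0.04 (adjusted p = 0.00508).

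Among the other lists, 3 had a member whose rhythm passed when adjusted over the list alone. These were Ugt35B1 among 88 detoxification genes (list-alone adjusted p = 0.0300), the cuticle protein gene Cpr67B among 18 cuticle and pigment genes (0.25 ± 0.04 log2, hour 4.09, list-alone adjusted p = 0.01) and Cyp4d21, a gene with male-biased expression, among 3 male markers (0.87 ± 0.22, hour 18.9, list-alone adjusted p = 0.0256). No member passed in the lists of phototransduction (24 measured), chaperones (10), antimicrobial and immune genes (15), fat body and lipid genes (28), carbohydrate and feeding genes (36), neurons and synapses (34), glia (19), female markers (7), ovary (17), testis and accessory gland (23), flight muscle (20), midgut (33), cytosolic ribosomal proteins (37) and oxidative phosphorylation (72). As whole lists, phototransduction genes and flight muscle genes were higher in mid-day than mid-night, with medians of 0.07 and 0.15 log2 (camera, adjusted p = 0.0130 and 0.0170), and higher at dusk than dawn, with dawn over dusk medians of −0.05 and −0.14 (adjusted p = 0.0103 and 0.00419). With an estimated correlation none of these 4 calls held (adjusted p = 0.216 for both phototransduction calls and 0.437 or more for both flight muscle calls). The mid-day calls of both lists were lost with the 5′ minus 3′ signal as a covariate (medians of 0.02 and 8.27e-04 log2, adjusted p = 0.159 and 0.459). The dawn over dusk calls were kept with it, with medians of −0.07 for phototransduction and −0.08 for flight muscle, the latter nearer to 0 than before (adjusted p = 0.0231 and 0.0226). Dawn over dusk, the lists of clock genes (−0.06) and chaperones (−0.11) were lower, and those of midgut (0.05), testis (0.03), ribosomal protein (0.08), detoxification (0.04) and immune genes (0.04) were higher, with adjusted p from 0.00218 to 0.0422. The midgut mean stood out on DD 2 (6.37 log2, against 5.90 to 6.01 on the other DD arrays and 5.92 to 6.05 in LD). That of testis genes stood out on DD 22 (4.45 against 4.16 to 4.24 on the other DD arrays). List tests were not repeated with single arrays left out, so these shifts may lean on 1 array. Adding the 5′ minus 3′ signal as a covariate ended the calls of the chaperone and testis lists (adjusted p = 0.0502 and 0.192), where the chaperone median stayed at −0.11 and the testis median went to 0.02. Cuticle and pigment genes (0.03) and oxidative phosphorylation genes (0.05) were higher in mid-day (adjusted p = 0.0103 and 0.0416). None of the 25 list shifts called over 20 lists and 4 contrasts held with an estimated correlation; for the rhythm axes those adjusted p lay between 0.216 and 0.698.

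Rhythms were next fitted to each day on its own curve, with 1 estimate of the spread for both. In LD, tim rose and fell with an amplitude of 1.21 ± 0.10 log2 and a peak at hour 15.3 (limma, adjusted p = 0.00863). CG11413 (1.06 ± 0.09, hour 9.54, adjusted p = 0.00863) and CG12998 (1.08 ± 0.10, hour 9.16, adjusted p = 0.0124) peaked before dusk. Act88F, the actin of the indirect flight muscle, peaked at hour 13.2 (1.00 ± 0.09, adjusted p = 0.0155), Slob at hour 15.3 (0.64 ± 0.06, adjusted p = 0.0159) and vri at hour 13.6 (0.84 ± 0.09, adjusted p = 0.0265). The mean of the flight muscle list, which holds Act88F, was 7.415 log2 at LD 2 and 8.365 at LD 14. Thorax muscle carried over with the heads cannot be told apart here from a rhythm within the head. The 7th call was a dimmer probe set of Tsp, the thrombospondin gene (0.58 ± 0.05, adjusted p = 0.00863), where the brightest Tsp probe set had 0.13 ± 0.06 (adjusted p = 1.0). The unadjusted p was under 0.05 for 790 probe sets. The calls depended on single arrays: there were 16 without LD 2, 37 without LD 6, 2 without LD 10 or LD 14, 1 without LD 18 and 0 without LD 22, where the adjusted p of the 6 genes named for LD lay between 0.0768 and 0.105. Without LD 10, CG11413, CG12998, Slob and vri lost their calls (0.0638 to 0.0891), and without LD 18 all but CG11413 did (0.055 to 0.115). Without LD 14 the adjusted p was 0.112 for tim and Act88F, 0.203 for Slob and 0.588 for vri. The call of vri also ended without LD 2, DD 2, DD 6 or DD 10 (0.0602 to 0.104), and the calls of vri and Act88F ended without DD 22 (0.0507). With the 5′ minus 3′ signal as a covariate 4 probe sets were called, and the calls of Act88F, Slob and vri were lost (0.0693, 0.0733 and 0.11), with amplitudes about as large as before (1.02, 0.65 and 0.84 log2). Slob also lost its call with an intensity trend and a robust prior (limma, adjusted p = 0.0845). With the 6 LD arrays alone 1 was called.

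In DD, 0 probe sets passed (limma), and 1609 had an unadjusted p under 0.05. The smallest adjusted p was 0.0720, for CG13305 (amplitude 0.71 ± 0.07 log2, peak at hour 3.08) and for vri (0.87 ± 0.09, hour 13.8). tim had an amplitude of 0.85 ± 0.10 and a peak at hour 14.4 (adjusted p = 0.0931), phu had 0.81 ± 0.09 at hour 6.89 (0.0931), and the muscle actin gene Act87E had 0.82 ± 0.11 at hour 5.87 (0.171). There were 14 calls without LD 2, 7 without LD 22 and 1 without DD 18, and 0 without each other array.

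No probe set passed the test of whether the rhythm differed between the days (limma, 0 of 13966, with 1391 at an unadjusted p under 0.05), so the calls in LD were not shown to be lost in DD. With the 5′ minus 3′ signal as a covariate 420 had an unadjusted p under 0.05, where uniform p-values would give 698. The median standard error went from 0.103 to 0.139 log2. The difference vector of tim was 0.43 ± 0.14 log2 (adjusted p = 0.451) and that of vri 0.05 ± 0.12 (adjusted p = 0.979). The smallest p-values belonged to muscle actins. The curve of Act87E peaked at hour 13.5 in LD and at hour 5.87 in DD, with a difference of 1.40 ± 0.15 (adjusted p = 0.107), that of Act79B at hours 13.3 and 6.30 (1.51 ± 0.18, adjusted p = 0.115), and Act88F had amplitudes of 1.00 ± 0.09 and 0.23 ± 0.09 (1.21 ± 0.13, adjusted p = 0.107). The probe sets of Act87E and Act79B rose and fell together over the arrays, so they may not be separate results. With the 5′ minus 3′ signal as a covariate their differences were 1.21 and 1.25 (limma, adjusted p = 0.75 and 0.812). CG11413 had 1.06 ± 0.09 in LD and 0.11 ± 0.09 in DD (0.99 ± 0.12, adjusted p = 0.132), and phu had a difference of 0.96 ± 0.13 (adjusted p = 0.217). There were 6 calls without LD 2, 12 without LD 6 and 3 without LD 22.

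The mean level over the day in darkness was then compared with that over the light/dark day, a comparison in which the light regime cannot be told apart from the order of the days. A few cuticle protein genes and an antimicrobial peptide gene fell. Of 90 genes with symbols of the Cpr, Ccp, Lcp, Twdl and Edg cuticle protein families, a set chosen after the values were seen that does not hold Acp1, 55 had a lower estimate in DD and 2 were called, with a median of −0.02 log2. Acp1 (NCBI gene 34052), which encodes a cuticle protein, went from 12.08 ± 0.86 log2 in LD to 8.35 ± 0.40 in DD (SD, n = 6 each), and so fell by 3.73 ± 0.32 log2 (SE), a 13.2-fold difference (limma, adjusted p = 0.00185). The cuticle protein genes Cpr100A and Cpr92F fell by 1.80 ± 0.25 and 1.48 ± 0.20 log2 (adjusted p = 0.0141 and 0.0134), and Vajk3 fell by 2.36 ± 0.32 (adjusted p = 0.0134). DptB, which encodes the antimicrobial peptide Diptericin B, fell by 1.80 ± 0.24 log2, a 3.49-fold difference (adjusted p = 0.0134), and the storage protein gene Lsp2 fell by 1.19 ± 0.18 (adjusted p = 0.0335). CG7214 and CG8736 fell by 3.41 ± 0.43 and 3.12 ± 0.37 log2, a 10.6-fold and an 8.68-fold difference (adjusted p = 0.0115 and 0.0108), CG31676 fell by 1.11 ± 0.14 (0.0115) and CG13056 fell by 0.68 ± 0.09 (0.0134). CG8654 rose by 0.64 ± 0.07 and the glucuronosyltransferase gene Ugt36E1 by 0.45 ± 0.07 (adjusted p = 0.00723 and 0.0251).

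In all, 18 probe sets were lower in DD and 3 higher, and 952 had an unadjusted p under 0.05. In 18 of the 18 lower ones every DD array lay below every LD array, which chance gives for 0.108% of unselected probe sets, whereas these had been selected for a lower level in DD. The call for Vajk2 (−1.87 ± 0.25 log2) and that for Fs(2)Ket (0.66 ± 0.09) came from dimmer probe sets, and their brightest probe sets did not pass (−0.48 ± 0.17 and 0.15 ± 0.15, adjusted p = 0.594 and 0.875). For CG31676 a dimmer probe set had −0.05 log2 (adjusted p = 0.912). With the 5′ minus 3′ signal as a covariate 26 probe sets were called, 19 of them among the 21, and Lsp2 was lost (adjusted p = 0.0880). The count was 13 without LD 18, 4 without DD 6 and 5 without DD 18. Of the 12 genes named for this comparison, 10 lost their calls without DD 6 and 9 without DD 18 (adjusted p from 0.0505 to 0.109). Lsp2 lost its call without any array other than LD 2 (0.0512 to 0.114), and Ugt36E1 lost its call without any other than LD 14 and DD 14 (0.0505 to 0.109). Cpr100A lost its call also without LD 10 or DD 10 (0.0592 and 0.0527), CG13056 also without LD 18 or DD 10 (0.0530 and 0.0538), Vajk3 without LD 18 (0.0502) and DptB without DD 22 (0.0531). With hour of day as a block 2 probe sets passed, and without the 4 arrays of lowest 5′ signal 0 of them did. With those 8 arrays the differences were about as large, at −3.87 for Acp1 (adjusted p = 0.0851), −3.84 for CG7214 (0.194) and −1.85 log2 for Cpr100A (0.329).

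**Figure D3:**
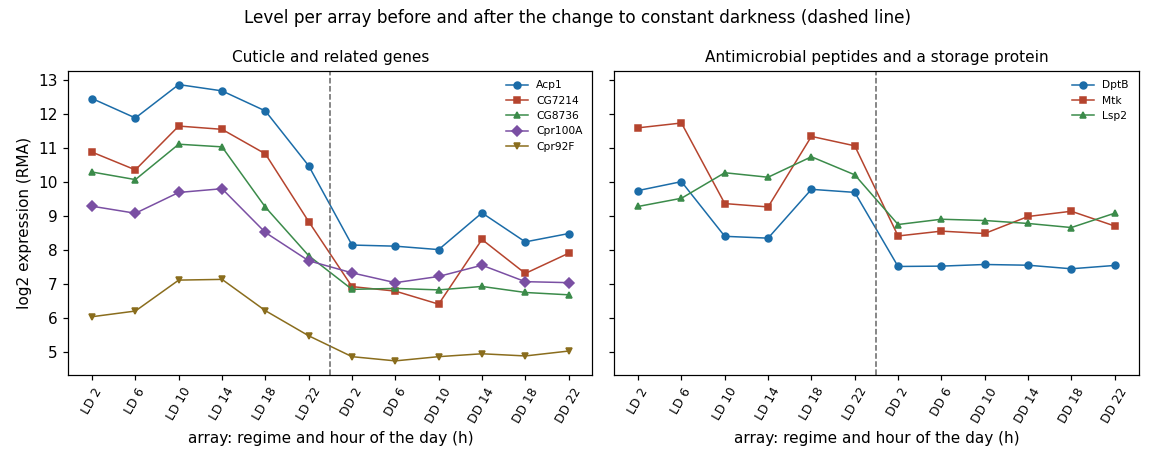
Log2 expression (vertical axis, RMA values) on each array in order of collection, with a dashed line at the change to constant darkness, for 5 cuticle and related genes on the left and for 2 antimicrobial peptide genes and a storage protein gene on the right. Every DD point of Acp1, CG7214, CG8736, Cpr100A, Cpr92F, DptB and Lsp2 lies below every LD point of the same gene.

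Of the gene lists, antimicrobial and immune genes had 1 member called lower in DD over all probe sets (DptB) among 15, and 3 when adjusted over the list alone. The others were the antimicrobial peptide gene Mtk (−2.01 ± 0.39 log2, list-alone adjusted p = 0.00215) and PGRP-SB1, a peptidoglycan recognition gene (−0.85 ± 0.21, 0.00914). The list median was −0.10 log2 (camera, adjusted p = 0.00135, and adjusted p = 0.254 with an estimated correlation). Flight muscle genes had 0 called and 3 lower when adjusted over the list alone, namely Mlc2 (−0.73 ± 0.16), Act88F (−1.17 ± 0.27) and Act79B (−1.19 ± 0.34), and 0 of the 20 members had a higher estimate in DD. Their median was −0.29 log2 (camera, adjusted p = 3.64e-06, and adjusted p = 0.254 with an estimated correlation), and −0.17 with the 5′ minus 3′ signal as a covariate. Ribosomal protein genes had a median of 0.19 log2, with 31 of 37 higher in DD (adjusted p = 7.79e-06, and adjusted p = 0.4 with an estimated correlation) and none past the threshold alone. Medians were −0.09 for neuron and synapse genes, −0.08 for cuticle and pigment genes, −0.07 for proteasome subunits and 0.04 for oxidative phosphorylation genes (camera, adjusted p = 0.00419, 0.0309, 0.0103 and 0.0422). With an estimated correlation the adjusted p of these 4 lay between 0.273 and 0.692. The cuticle, proteasome and oxidative phosphorylation calls were also lost with the 5′ minus 3′ signal as a covariate (0.0654, 0.145 and 0.0665), with medians of −0.09, −0.04 and 0.04, so the cuticle and oxidative phosphorylation shifts did not become smaller.

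Members passed when adjusted over the list alone in 5 further lists. tim was lower in DD among clock genes (−0.51 ± 0.13 log2, list-alone adjusted p = 0.0270), yellow-e among cuticle and pigment genes (−0.48 ± 0.12, 0.0383) and Lsp2 among fat body genes (0.00134), while the lysozyme gene LysS was higher among midgut genes (0.37 ± 0.08, 0.0237). Among female markers yl was higher (0.47 ± 0.14) and Sxl lower (−0.26 ± 0.08), both with list-alone adjusted p = 0.0216, and the list's median of −0.07 and mean of 0.02 differed in sign. The 10 lists of cell types and sexes were also compared as mean levels per array. None passed after adjustment over the 10 lists. The smallest p-values were those of neuron and synapse genes (5.60 ± 0.10 log2 in LD and 5.48 ± 0.06 in DD, SD, n = 6 each, two-sided exact permutation p = 0.0238), ovary genes (5.89 ± 0.05 and 5.96 ± 0.05, exact permutation p = 0.0325) and flight muscle genes (7.94 ± 0.34 and 7.53 ± 0.26, exact permutation p = 0.0411), each with adjusted p = 0.137. For lists of other body parts, such as flight muscle, these values cannot separate carry-over from a change within the head.

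The day-night difference in LD was last compared with that in DD, since light was on only at hours 2, 6 and 10 of LD. In this contrast, the mean of those hours minus the mean of hours 14, 18 and 22 is taken in each regime and the DD difference is subtracted from the LD difference. The transcripts of Ubi-p63E, a polyubiquitin gene, had the contrast furthest below 0, at −3.11 ± 0.70 log2 (SE, limma, adjusted p = 0.0464), followed by the amino acid transporter gene path (−2.37 ± 0.36, adjusted p = 0.0210) and CG4364 (−2.24 ± 0.35, 0.0210). The trehalose transporter gene Tret1-1 (−2.08 ± 0.36, 0.0264) and the phosphoglucomutase gene Pgm1 (−1.87 ± 0.29, 0.0210) were among the 10 lowest. The contrast was highest for CNBP (2.26 ± 0.36, 0.0217), CG17298 (2 ± 0.32, 0.0214), CG14989 (1.83 ± 0.39, 0.0406), Ref1, an RNA export factor gene (1.83 ± 0.24, 0.0179), and pAbp, the poly(A)-binding protein gene (1.69 ± 0.32, 0.0305). In all 299 probe sets passed, 110 with a higher and 189 with a lower contrast, and 2633 had an unadjusted p under 0.05.

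Some of these transcripts separated the arrays by their 5′ minus 3′ signal. CNBP lay between 10.4 and 10.7 log2 on the 4 arrays of lowest signal (LD 2, DD 14, DD 18 and DD 22) and between 8.96 and 9.57 on all others, and Ref1 between 7.80 and 8.46 against 6.74 to 7.64. Others overlapped, with path between 7.08 and 7.46 against 7.37 to 8.76 and Ubi-p63E between 9.15 and 9.99 against 8.73 to 11.5. With the signal as a covariate 0 of the 299 were called, while all 299 kept their sign. The median size of their contrast went from 0.95 to 0.75 log2, and the standard error grew 1.51-fold. Leaving out 1 array moved the count from 1 (without DD 2 or DD 6) to 1349 (without LD 6). It was 157 without LD 2, 29 without LD 14, 12 without LD 18, 15 without LD 22, 2 without DD 10 and 19 without DD 22. Hour-matched differences in a block of hour of day gave 114 calls, and the mid-day over mid-night axis of the rhythm gave 0 (limma). Ref1 lost its call without DD 2, DD 6 or DD 10 (adjusted p from 0.0526 to 0.0606), and each of the other genes named for this contrast lost its call without at least 5 of the arrays in turn. Other probe sets of the same gene had −2.25 log2 for Tret1-1 and 1.08 for jus, but −0.15 for Ttd14, 0.61 for pAbp, and 0.65 and −0.04 for CNBP.

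By list, neuron and synapse genes had 3 of 34 members called higher in this contrast over all probe sets and 3 when adjusted over the list alone, elav (1.34 ± 0.27 log2), Syn (1.34 ± 0.19) and Rdl (0.62 ± 0.12). Their median was 0.17 (camera, adjusted p = 0.0227, and adjusted p = 0.216 with an estimated correlation). Detoxification genes had a median of −0.21 (adjusted p = 1.88e-04, and adjusted p = 0.4 with an estimated correlation), with 1 of 88 members called lower, Cyp6a23 (−0.79 ± 0.17), and 4 when adjusted over the list alone. Testis and accessory gland genes had a median of 0.16 (adjusted p = 0.0103, and adjusted p = 0.691 with an estimated correlation), and the call was lost with the 5′ minus 3′ signal as a covariate (median −0.05, adjusted p = 0.940). The detoxification and neuron lists kept their calls with the covariate (medians of −0.21 and 0.13, adjusted p = 0.00173 and 0.0149), though not with an estimated correlation. Among phototransduction genes retinin was called higher (1.33 ± 0.23) and inaD lower (−1.26 ± 0.23), and 2 higher and 5 lower passed when adjusted over the list alone. The clock list had slmb, which marks proteins for degradation, called lower (−0.98 ± 0.18), while tim (−0.54 ± 0.68), vri (0.15 ± 0.66) and per (0.22 ± 0.23) did not pass. Tep4 and Rel among immune genes, Pepck2 among carbohydrate genes and ND-51 among oxidative phosphorylation genes were also called lower (−1.56, −0.99, −1.19 and −1.56 log2), and like every other probe set called in this contrast they did not pass with the covariate.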

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

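Of the tests in this part, both sign tests of light-dependent calls against the 5′ minus 3′ signal, the test of a continuing decline and every use of that signal as a covariate were chosen after the results were seen.

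A difference between the regimes was tested directly and passed for 299 probe sets, whose day-night difference in LD was unlike that in DD. The contrast, in log2, was lowest for Ubi-p63E (−3.11), path (−2.37), CG4364 (−2.24), CtsK1 (−2.23), P5CDh1 (−2.18), Tret1-1 (−2.08), Ttd14 (−2.06), Idh3g (−1.91), Sms (−1.88) and Pgm1 (−1.87). It was highest for CNBP (2.26), CG17298 (2), CG14989 (1.83), Ref1 (1.83), pAbp (1.69), CG13551 (1.68), Rm62 (1.57), Sec61beta (1.51), jus (1.49) and B52 (1.48).

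For 7 of these genes the array of LD hour 2 lay far from the other LD arrays, with a gap to the nearest of them, as a share of the range, above Dixon's critical value for 6 arrays. The share was 0.661 for CG4364, 0.652 for P5CDh1, 0.71 for Tret1-1, 0.664 for Idh3g, 0.698 for Sms, 0.651 for CNBP and 0.688 for Rm62. The same measure singled out DD 18 for CG12998 (0.644, at 4.09 against 4.37 to 4.52 log2) and LD 6 for CG31676 (0.709, at 7.98 against 7.01 to 7.29). It also singled out DD 2 for the mean of the midgut genes in DD (0.757, at 6.37 against 5.90 to 6.01) and DD 22 for the mean of the testis and accessory gland genes in DD (0.721, at 4.45 against 4.16 to 4.24). Of 132 groups of 6 arrays 11 were singled out in this way, and chance flags about 1 in 20 groups.

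The light-dependent calls may come from RNA integrity. LD 2 was the lit array with low mean 5′ signal, though only in actin and GAPDH. Its eIF-4a signal (−1.29) and that of DD 14 (−1.18) were the highest of all arrays, which goes against low integrity there. Of the 299, 91.97% (275), against 65.8% of all probe sets, differed between LD 2 and the other lit arrays in the direction of their contrast. Since LD 2 is itself part of that contrast, the share may be partly built in, but with LD 2 left out of the contrast and of the calling it was 92.99% (146 of 157), against 57.4% of all probe sets. With the signal as a covariate 0% of the calls passed, the median size going from 0.95 to 0.75 log2 while the standard error grew 1.51-fold. More of the loss thus came from the larger error than from the smaller size. The covariate cannot tell an effect of light from RNA integrity for these probe sets, since 3 of the 4 low arrays were the night arrays of DD. The error growth that would have left the covariate test open was set at over 1.5-fold, and the observed growth exceeded that only narrowly. No light was on in DD, so a day-night difference within DD is not a direct effect of light. The contrast was not tested in each regime apart. Within DD, CNBP lay between 9.11 and 9.21 log2 at hours 2, 6 and 10 and between 10.4 and 10.7 at the later hours. CG4364 lay between 6.68 and 6.78 against 4.91 to 5.36, but CG17298 between 7.53 and 7.62 against 7.30 to 7.44. Of 100 splits of the arrays, 2 gave as many calls as the real 299, namely the real one and another with 632. A random division seldom gives as many, but chance is not excluded, since the splits treat arrays as exchangeable and consecutive ones resembled each other. The split with 632 calls points to a structure of the samples. Its contrast set LD 2, LD 10, LD 22, DD 14, DD 18 and DD 22, with all 4 arrays of lowest 5′ signal among them, against the rest.

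The lower level in DD of 18 probe sets, among them Acp1, CG7214, CG8736, Cpr100A, Cpr92F and DptB, was weighed against RNA integrity, a decline over both days, and chance. After the 5′ minus 3′ signal was added as a covariate 88.89% (16) still passed, which argues against RNA integrity as the whole cause. The slope on hour was negative for 17 of 18 within LD but for 55.56% (10 of 18) within DD, with medians of −0.50 and −0.01 log2 per 24 h, so a decline that continued at 1 rate is not borne out. The median step from LD 22 to DD 2 was −0.96 log2, which is partly built in, since these probe sets were selected for a difference between the days. LD 22 lay below all earlier LD arrays for 8 of 18, and the median of LD 22 minus the earlier LD arrays was −0.23. Over LD 14, LD 22 and DD 2, CG8736 read 11.03, 7.83 and 6.84 log2, and Cpr100A 9.80, 7.68 and 7.33, so more of that fall came before DD. Lights were already off at LD 14 and stayed off from there on, so a fall before DD is not a fall before darkness. Acp1 (12.68, 10.48 and 8.15) fell about as much after LD 22 as before, and DptB (8.35, 9.70 and 7.52) fell only after it. A step between the days and a decline that levelled off therefore cannot be told apart for the 18 as a set, whose members differed in when they fell. Only the real of 100 splits gave as many as 21 calls, and the highest other gave 1, so a random split of the arrays seldom gives as many. The darkness itself, the age of the flies and differences between the collections of the days may each be involved, and all follow the order of the days.

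The higher level of proteasome subunits near dusk than dawn kept 96.17% of its median size with the 5′ minus 3′ signal as a covariate, which argues against RNA integrity as its cause on that axis. On the mid-day over mid-night axis the median went from 0.08 to 0.04 log2, so RNA integrity stays open there. The list's call did not hold with an estimated correlation (adjusted p = 0.216), and 10 of the 40 subunits had the opposite sign. Of 100 orders of the hours, 3 gave as many as the 11 members with an unadjusted p under 0.05, the highest other giving 16. The permutation p was 0.03 for this list and 0.2 after adjustment over the lists, so chance is not excluded. A daily rhythm of proteasome transcripts is a candidate explanation, found and tested on the same 12 arrays.

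Among 100 orders of the hours, only the real one gave as many as the 3 daily rhythm calls (highest other 1) or as the 7 calls in LD (highest other 6). Random orders thus seldom give as many. They also break up the likeness of consecutive arrays, so the test cannot tell a rhythm in LD from a drift within that day. The LD count was close to that of another order and was 0 without LD 22. For the rhythm in DD and the difference of rhythm the real count was 0 (limma, 1609 and 1391 probe sets at an unadjusted p under 0.05, and 284 and 420 with the 5′ minus 3′ signal as a covariate). Every order or exchange reaches a count of 0, so 100 of 100 orders and 32 of 32 exchanges of LD and DD within hours decide nothing about chance. The highest other count was 1 for DD and 104 for the difference, where 4 exchanges gave a call, which points to a structure of the samples.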

How the results depend on the processing

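The covariate and the omission of the 4 arrays of lowest 5′ signal were chosen after the results were seen. The cause was not tested for any change given here, unless the alternative's construction shows it. Of the counts under other settings, 83 stayed within 1.5 times the original, 26 fell further and 9 rose further. The 83 include counts of 0 that stayed at 0 and could not fall. They also include daily rhythm counts that went from 3 to 2, which is at the limit. Of the values of single genes, 3070 kept their direction and side of the threshold, 326 lost and 18 gained a call, and 15 reversed. None of the 15 was past the threshold. The 3070 include values of genes that were not called originally and could not lose a call, so they do not measure how well calls held. Of the 20 genes named for the light-dependent difference, 20 lost their calls with the mid-day axis by regime and 10 with hour-matched differences. With quantile normalization again or centred arrays 0 of the 20 lost them. Of the shifts of gene lists, 42 kept and 33 lost their call.

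The brighter probe sets, quantile normalization again, centred arrays and a robust prior gave between 2 and 3 daily rhythm calls, 5 and 7 in LD, 17 and 22 for mean level and 279 and 336 for the light-dependent difference. Hour as a factor gave 0 daily rhythm calls (limma, against 654 at an unadjusted p under 0.05 in the cosine fit) and the 6 LD arrays alone 1, with fewer residual degrees of freedom in both. Hour of day as a block gave 2 calls for mean level and 114 for the light-dependent difference, though the deviations of arrays of the same hour had r from only −0.44 to 0.15, and 0 of the 12 arrays were nearest to the array of their hour. The mid-day axis by regime gave 0 light-dependent calls. An estimated correlation left 0 of the 25 list calls.

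With the 5′ minus 3′ signal as a covariate, there were 4 calls in LD and 0 light-dependent calls. Without the 4 arrays, 1 daily rhythm call, 3 in LD and 0 for mean level were left, with 8 arrays. No array of the DD night remained, so the other comparisons were not run there.

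Leaving out 1 array gave from 2 to 3 daily rhythm calls, 0 (LD 22) to 37 (LD 6) in LD, 0 to 14 (LD 2) in DD, 0 to 12 (LD 6) for the difference of rhythm, 4 (DD 6) to 26 (LD 22) for mean level and 1 (DD 2 or DD 6) to 1349 (LD 6) for the light-dependent difference.

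A reversed rhythm means a peak moved by more than 6 h. That held for Yp3 after quantile normalization again (amplitude 0.04862), for tws between arrays left out (0.01562 to 0.1139), for dco, slmb and wdb with the covariate (0.1106, 0.05217 and 0.02585) and without the 4 arrays (0.1457, 0.1213 and 0.04206). The mean level difference changed sign for Cyp4d21 (−0.04421 to 0.4064) and Obp99b (−0.07885 to 0.2809) between arrays left out. It did so without the 4 arrays for slmb (0.03458), trp (0.01426) and Hsc70-3 (0.01821).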

Other observations

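The cuticle family list and the comparison of consecutive arrays were chosen after the results were seen. Among 90 genes with symbols of the Cpr, Ccp, Lcp, Twdl and Edg cuticle protein families, 55 had a lower estimate in DD, 2 were called over all probe sets and 7 passed when adjusted over the list alone, all lower. The median was only −0.02 log2 (camera p = 0.00198, and p = 0.34 with an estimated correlation).

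Arrays collected one after the other resembled each other more than the rest. The correlation of their deviations from the mean of all arrays averaged 0.165, against −0.136 for pairs that were not consecutive (permutation p = 0.00121). A difference between the days or a slow rhythm adds to this measure.

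The antimicrobial peptide genes DptB and Mtk varied together within LD. DptB was at 8.40 and 8.35 log2 at hours 10 and 14 of LD and between 9.70 and 10.01 at the other LD hours, and Mtk at 9.37 and 9.27 against 11.1 to 11.7. In DD, DptB lay between 7.45 and 7.57 and Mtk between 8.41 and 9.14. CG17298 went from 10.6 at LD 2 to 7.54 at LD 22 and lay between 7.30 and 7.62 in DD.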
